A study of Homo sapiens with 6 samples.

How the data were processed

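Gene expression was measured in L-428, a cell line of Hodgkin Reed-Sternberg (HRS) cells, the malignant cells of classical Hodgkin lymphoma. Per the labels, cells were spin-infected with 8 µg/ml polybrene, sorted for the GFP marker of transduction after 72 hours and frozen, and biotinylated cRNA was made from 200 ng of total RNA. There were 3 arrays of cells with an shRNA against BATF3, an AP-1 family transcription factor, and 3 arrays of cells with a non-targeting shRNA against luciferase, numbered 1 to 3 in each group. Each group carried a single hairpin, and the labels do not say whether the numbers stand for separate transductions. The p-values of single genes thus measure only the spread between these samples, which may be technical.

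The deposited values are log2 signals of 53617 probe sets on 6 arrays, from 1.66 to 14.6, with array medians between 5.12 and 5.16. The base of the logarithm was read from the values, since natural logarithms of a 16-bit scan end at 11.1. The submitters' processing notes name MAS5 without saying what it was used for, and the normalization is not given in the sources used here, so the values were used as deposited. The platform annotation given for these probe sets named 16098 of them (30.0%), each with a single gene, for 14884 symbols, of which 779 had several probe sets. All 16098 Entrez identifiers matched the RefSeq gene table and no symbol changed. The other 37519 probe sets were unnamed here. BATF3, BATF, STAT6 and TNFRSF8 were not among the named genes, so they are not analysed here, and the knockdown of BATF3 was not checked on the arrays. No 3' to 5' control probe sets were named either, so RNA quality was not analysed here. The number of arrays limits the precision.

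For each gene the probe set with the highest mean signal was used, and genes at or above the median of all probe sets (a log2 signal of 5.14) were kept, which left 10028 genes, 8817 of them protein-coding. Differences are knockdown minus control, fitted with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with an intensity trend), with Benjamini-Hochberg adjustment over genes and a threshold of 0.05. The model, the gene lists, the rule for named genes and most alternatives were set before the data were examined, with no term for the replicate number. The labels do not say that the replicate numbers pair the arrays, so the pairing rests on the values. Deviations from the group means correlated across genes between arrays of the same number at 0.41 to 0.61. Those between arrays of different numbers, which positive same-number values push down since deviations cancel within a group, were −0.43 to −0.03. Whole-array correlations were highest between same-number arrays for numbers 2 and 3 (0.9909 and 0.9917) but not for number 1. BATF3 shRNA array 1 correlated at 0.9900 with array 3 of its own group and at 0.9899 with control 1. Results with the replicate number as a block, called the paired fit, are therefore given beside those without it wherever the calls differ. Of 29 gene lists written from general knowledge, 25 had at least 5 measured genes and were tested with limma's camera at a preset correlation of 0.01, adjusted over the 25 lists, and again with an estimated correlation and with fry. Camera sets a list's members against the other genes. At the preset correlation its p rests on the spread between genes and on that assumed value, so it does not measure reproducibility between arrays. The plasma cell, MHC class I, MHC class II and myeloid and dendritic cell lists had 4, 3, 1 and 4 measured genes and were not tested.

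Named genes were 10 fixed genes (BATF3, MYC, BATF, JUN, JUNB, IRF4, STAT3, STAT5A, STAT6 and TNFRSF8), up to 12 genes per direction that passed with the groups apart, or the 5 with the smallest p per direction where none passed, and up to 2 members with the smallest p per list. The genes of the paired fit, and the list members that passed in it, were named after their values had been seen. The model was tested on simulated data for the 10028 genes with 200 changed genes: without the block it recovered 13 of 100 genes changed by a log2 of 0.5 and 74 of 100 changed by 1, and with the block 91 and 100, with 6 false calls. The noise was drawn independently for each gene from the variances of the paired fit, with a replicate effect added. The simulation thus assumes the paired model, and is no support for the genes called with it. Alternatives were quantile normalization, other variance priors, other signal filters, means over probe sets, probe sets in place of genes, a size threshold, and each array left out. Other pseudocounts and the removal of cross-hybridising probe sets did not apply, since the values are already logarithms and the probe sets carry no such suffix. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.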

Results

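Transcript levels were compared between L-428 Hodgkin lymphoma cells carrying an shRNA against BATF3 (3 arrays) and cells carrying a non-targeting shRNA (3 arrays), sorted as transduced cells 72 hours after infection. The comparison asks which transcripts depend on BATF3 in these cells, and the study's title puts MYC activity downstream of it. Values are log2 signals of single arrays, with 10028 genes in the fit. BATF3 itself is not analysed here, so the arrays are described as labelled.

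In the model set in advance, which has no pairing, 0 of 10028 genes passed limma's test. With the arrays paired by replicate number, 20 genes passed. There were 13 higher and 7 lower in the BATF3 shRNA arrays, each with the same direction in 3 of 3 pairs. That shared direction is no separate support, since the test selects on the same 3 pairs. In some of the 20, such as SLFN5 and MIR196A1, the arrays of the groups overlapped in signal. The lysophospholipid acyltransferase gene LPGAT1 (probe set 16699009) fell most, 1.77-fold. It went from a mean log2 signal of 8.56 ± 0.16 to 7.74 ± 0.24 (SD, n = 3), a difference of −0.82 ± 0.077 (SE; adjusted p = 0.00932). The acyl-CoA thioesterase gene ACOT9 fell 1.58-fold, the CREB-like gene CREBL2 1.56-fold, the gene of the mRNA decay factor PATL1 1.40-fold and the noncoding RNA NORAD, which binds Pumilio proteins, 1.28-fold. ROGDI and the microRNA gene MIR196A1 fell by 0.65 and 0.73 on the log2 scale. SLAMF1, a lymphocyte surface receptor, rose 1.60-fold, the zinc finger and homeobox gene ZFHX3 1.52-fold, the interferon-induced SLFN5 1.46-fold, the interferon regulatory factor gene IRF1 1.44-fold and the chemoattractant receptor gene GPR15 1.40-fold. SH3RF1, ERLIN1, the sphingosine-1-phosphate lyase gene SGPL1, the monoamine oxidase gene MAOA, SEPHS1 and LINC00636 rose by log2 differences of 0.52, 0.50, 0.46, 0.43, 0.40 and 0.61. ANXA8 and ANXA8L1 also passed, at 0.50 and 0.58, but are near-identical copies whose probes may not tell them apart.

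**Figure D1:**
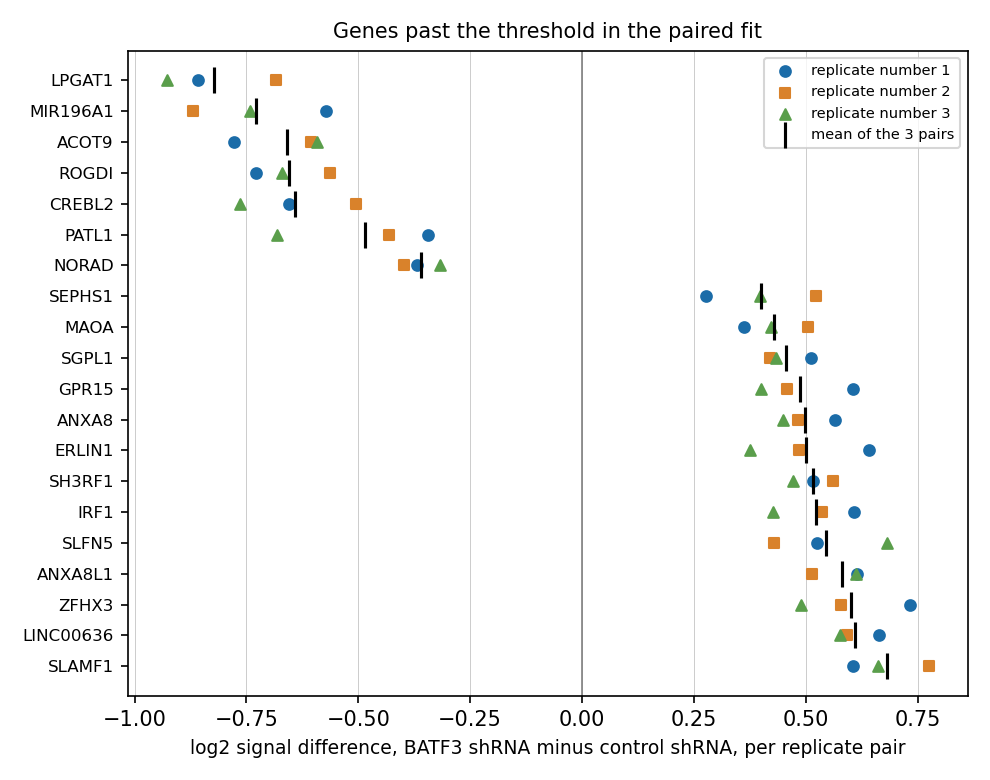
Log2 signal difference (BATF3 shRNA minus control shRNA, x axis) of the 20 genes that passed in the paired fit (y axis), with 1 point per replicate pair and a bar at the mean of the 3 pairs. LPGAT1 has the lowest mean at −0.82 and SLAMF1 the highest at 0.68, and in each gene the 3 points lie on the same side of 0.

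Without the pairing, 0 of 10028 genes passed in limma, with 343 genes at an unadjusted p under 0.05 where chance gives 501 and a lowest adjusted p of 1.00. The paired fit had 1202 genes at an unadjusted p under 0.05, 590 higher and 612 lower. The genes with the smallest p without the pairing were SH3RF1, ALOX15, ZFHX3, PRAMEF22 and TRIM10 on the higher side, with log2 differences of 0.52, 0.61, 0.60, 0.63 and 0.47. On the lower side they were ROGDI, LPGAT1, PATL1, MIR4530 and TMED8, at −0.65, −0.82, −0.49, −0.55 and −0.39. No gene differed by a log2 of 1 or more. The paired calls rest on few arrays, since 4 genes passed without the pair of replicate 1, 100 without that of replicate 2 and 0 without that of replicate 3. The 20 also became 0 without the intensity trend, 1 without a signal filter, 0 among probe sets and 0 with the number as a random block.

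MYC target genes were lower as a list in the BATF3 shRNA arrays by a small amount, and passed in camera at the preset correlation only. MYC itself did not pass. MYC (probe set 17072669) had a mean log2 signal of 10.00 ± 0.30 against 10.21 ± 0.20 in the control arrays (SD, n = 3). The difference was −0.20 ± 0.16 (SE) and did not pass (adjusted p = 1.00, and 0.282 in the paired fit). The 3 pairs lay at −0.24, −0.02 and −0.35. Of 38 measured MYC target genes, 33 lay below 0, and the list fell by a mean log2 of 0.09 (camera adjusted p = 0.0107, and 0.719 with an estimated correlation). Among the 10 splits of the 6 arrays into 3 and 3, 4 gave this list a camera p as small, counting the real one. The others of those 4 kept both arrays of replicate number 1 on 1 side. MYBBP1A, IPO4 and the spermidine synthase gene SRM, at −0.33, −0.25 and −0.26, passed in the paired fit when adjusted over the list alone. Ribosome biogenesis genes, which share 10 members with the MYC targets, fell by a mean of 0.09 with 30 of 33 below 0 (adjusted p = 0.0107; adjusted p = 0.719 with an estimated correlation). Their smallest p values were those of NAT10 and PWP2, at −0.26 and −0.27, and NAT10 and BOP1 (−0.32) passed in the paired fit adjusted over the list alone. Purine and pyrimidine synthesis genes fell by a mean of 0.10 with 14 of 17 below 0 (adjusted p = 0.0132; adjusted p = 0.731 with an estimated correlation). PFAS and DHODH, at −0.31 and −0.34, passed in the paired fit adjusted over the list alone.

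Amino acid stress genes formed the most lowered list. Of 14 measured targets of ATF4 and the integrated stress response, 13 lay below 0, and the list fell by a mean log2 of 0.17 (adjusted p = 0.0107; adjusted p = 0.265 with an estimated correlation). In the paired fit 6 of them fell when adjusted over the list alone, among them the serine synthesis genes PSAT1 (−0.42) and PHGDH (−0.15), the asparagine synthetase gene ASNS (−0.32), CTH (−0.25), ATF5 (−0.22) and SESN2 (−0.28). ATF3 went the other way and rose by 0.33. Cytosolic aminoacyl-tRNA synthetase genes fell by a mean of 0.08 with 15 of 17 below 0 (adjusted p = 0.0146; adjusted p = 0.478 with an estimated correlation). AARS1 and GARS1, at −0.25 and −0.14, had the smallest p without pairing, MARS1 stood at −0.22, and AARS1 passed in the paired fit adjusted over the list alone.

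Across these 5 lowered lists, no member passed without pairing, adjusted over all genes or adjusted over the list alone, and none passed over all genes in the paired fit. The integrated stress list passed whichever array was left out. The MYC target, ribosome biogenesis, synthetase and nucleotide lists did not pass without BATF3 shRNA array 1, at −0.03 (adjusted p = 0.739), −0.03, −0.06 and −0.04. They did not pass without control array 2 either, at −0.06, −0.04, −0.06 and −0.05. A single array left out leaves its partner's replicate effect in the difference. In the paired fit without the whole pair of replicate 2, MYC targets (−0.10, adjusted p = 0.00601), ribosome biogenesis (−0.10) and nucleotide synthesis (−0.12) passed and the synthetases (−0.08, adjusted p = 0.109) did not. Without the pair of replicate 1 none of these 4 passed (adjusted p = 0.0862 to 0.156), while the integrated stress list passed whichever pair was left out.

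Immune signalling and Hodgkin cell genes were higher as lists in the BATF3 shRNA arrays by small amounts, and passed in camera at the preset correlation only. The NF-kB target list rose by a mean log2 of 0.11 with 15 of 18 genes above 0 (adjusted p = 0.0107; adjusted p = 0.265 with an estimated correlation). CFLAR, an inhibitor of caspase-8, stood at 0.26 and TNF at 0.15. In the paired fit 5 of its genes rose when adjusted over the list alone, which were CFLAR, TRAF1 (0.19), EBI3 (0.21), BCL2A1 (0.23) and the chemokine gene CXCL10 (0.48). The list of Hodgkin Reed-Sternberg features rose by 0.10 with 14 of 18 above 0 (adjusted p = 0.0107; adjusted p = 0.478 with an estimated correlation). The kinase gene JAK2 (0.38), the costimulatory ligand gene CD80 (0.45), IRF4 (0.18) and TRAF1 passed in the paired fit adjusted over the list alone. JAK-STAT feedback and target genes rose by 0.10 with 13 of 16 above 0 (adjusted p = 0.0117; adjusted p = 0.265 with an estimated correlation). Its members CISH (0.31), PIM2 (0.39), STAT3 (0.17) and the survival genes MCL1 (0.21) and BCL2L1 (0.22) passed in the paired fit adjusted over the list alone. Cytokine and chemokine genes, 4 of which are also NF-kB targets, rose by 0.15 with 11 of 12 above 0 (adjusted p = 0.0125; adjusted p = 0.265 with an estimated correlation). CSF1 (0.33) and CXCL10 passed in the paired fit adjusted over the list alone, and TNF and EBI3 had the smallest p without it. Interferon-stimulated genes rose by 0.07 with 17 of 25 above 0 (adjusted p = 0.0453; adjusted p = 0.719 with an estimated correlation), and did not pass without a signal filter (adjusted p = 0.0866). Adjusted over the list alone in the paired fit, IFI44L (0.42), USP18 (0.26), XAF1 (0.28) and IRF9 (0.30) rose and DDX60 (−0.35) fell. Mitosis genes rose by 0.05 with 25 of 38 above 0 (adjusted p = 0.0125; adjusted p = 0.719 with an estimated correlation). CKS2 stood at 0.24 and BUB1 at 0.17, and no member passed adjusted over the list alone.

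The Hodgkin list shares 4 members with the cytokine list, 3 with the JAK-STAT list and 2 with the NF-kB list. With every member held by more than 1 list left out, the NF-kB list stood at 0.03 over 10 genes (adjusted p = 0.673). The cytokine list, with 5 genes left, stood at 0.15 (adjusted p = 0.101), and the interferon list, which lost no member, was at 0.07 as before (adjusted p = 0.0553). In these 6 raised lists no member passed without pairing, adjusted over all genes or adjusted over the list alone, and none passed over all genes in the paired fit. Without BATF3 shRNA array 1, the adjusted p was 0.111 for NF-kB targets and 0.0522 for each of the Hodgkin, JAK-STAT, cytokine and mitosis lists. Calls also ended without control 1 for JAK-STAT (0.0505), cytokines (0.177), mitosis (0.221) and interferon (0.642), and without control 2 for interferon (0.159) and control 3 for the Hodgkin list (0.0911). They ended without BATF3 shRNA array 2 for the Hodgkin, mitosis and interferon lists (0.0561 each), and without array 3 for cytokines (0.148) and interferon (0.478). In the paired fit with whole pairs left out, none of the 6 passed without replicate 1 (adjusted p = 0.0591 to 0.320), all but JAK-STAT (0.0518) and interferon (0.0853) passed without replicate 2, and all 6 passed without replicate 3.

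**Figure D2:**
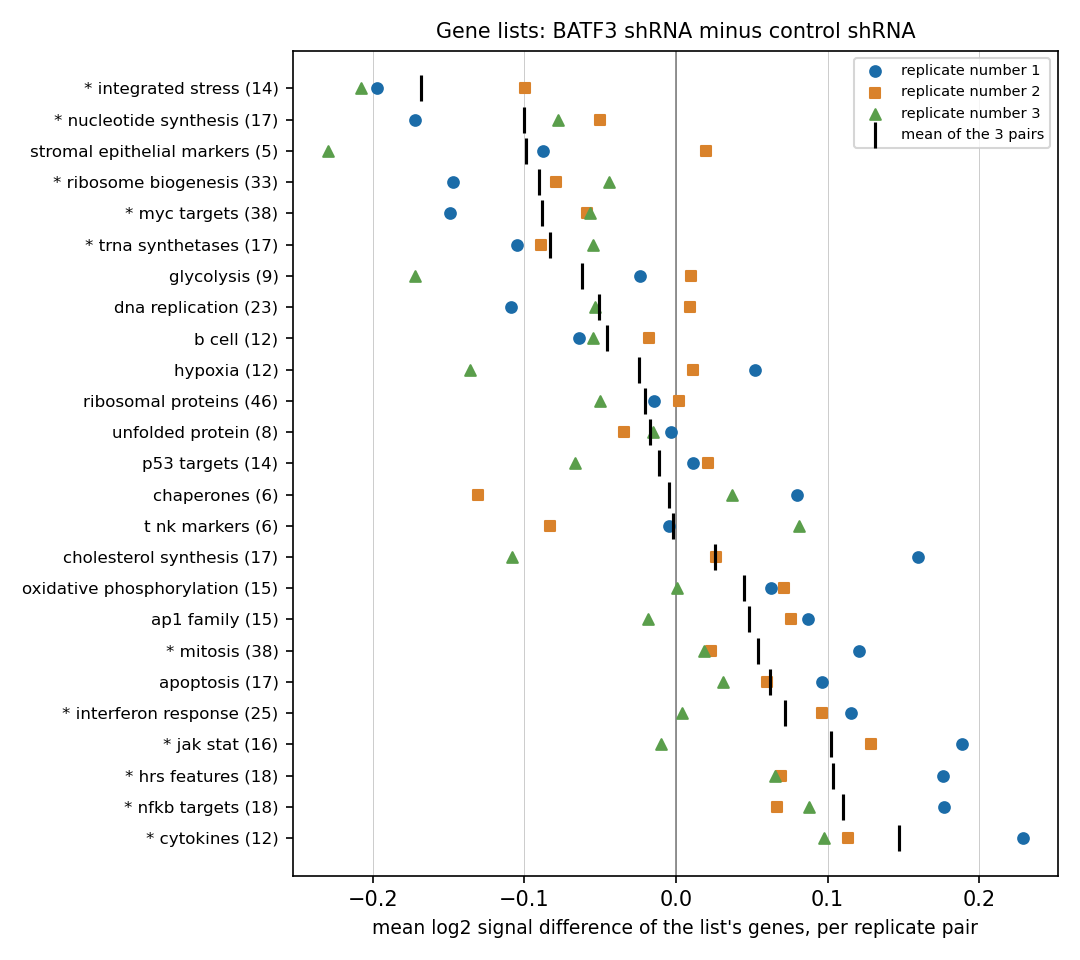
Mean log2 signal difference (BATF3 shRNA minus control shRNA, x axis) of the genes of each of the 25 tested lists (y axis, with the number of measured genes), with 1 point per replicate pair and a bar at the mean of the 3 pairs; asterisks mark the 11 lists that passed in camera without pairing. The integrated stress list has the lowest mean, −0.17, and the cytokine list the highest, 0.15, while the JAK-STAT list passed although its pair of replicate 3 lies at −0.01.

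Of the AP-1 and partner genes fixed in advance, JUN, JUNB and STAT5A had log2 differences of 0.16, 0.07 and 0.07, and none of them passed, nor did IRF4 or STAT3 over all genes (paired adjusted p = 0.165 and 0.291). The list of AP-1 and interferon regulatory factor genes did not pass at a mean of 0.05 (adjusted p = 0.144), and ATF3 and IRF4 rose in the paired fit when adjusted over the list alone. Genes of the BCL2 family, caspases and death receptors had a mean of 0.06 (adjusted p = 0.0584) and passed in the paired fit (adjusted p = 0.0378, and 0.610 with an estimated correlation). There CFLAR, MCL1, BCL2L1 and BCL2A1 rose when adjusted over the list alone, and the NF-kB or JAK-STAT list also holds each of them. With members held by other lists left out, the apoptosis list stood at −0.01 over 8 genes (camera adjusted p = 0.980 without pairing). DNA replication genes had a mean of −0.05 (adjusted p = 0.102), with MCM2 at −0.29 and MCM6 at −0.22. In the paired fit MCM2 fell and the cyclin gene CCNE2 (0.41) rose when adjusted over the list alone. B cell programme genes, which Hodgkin cells largely lack, had a mean of −0.05 (adjusted p = 0.850), and the complement receptor gene CR2 (−0.62) fell in the paired fit when adjusted over the list alone. Oxidative phosphorylation, ribosomal protein, glycolysis and cholesterol synthesis genes had means of 0.05, −0.02, −0.06 and 0.03 (adjusted p = 0.216, 0.531, 0.564 and 0.573). The mevalonate pathway gene PMVK (−0.38) fell in the paired fit when adjusted over the cholesterol list alone. Chaperone, unfolded protein response and p53 target genes had means of −0.00, −0.02 and −0.01 (adjusted p = 0.893, 0.893 and 0.986). Markers of other cell types did not pass either: fibroblast and epithelial markers had a mean of −0.10 (adjusted p = 0.564), and T and NK cell markers a mean of −0.00 although camera ranked them upward (adjusted p = 0.986). Hypoxia genes likewise had a mean of −0.02 with an upward rank (adjusted p = 0.986). With only genes above the 75th percentile of signal, the AP-1, DNA replication and apoptosis lists passed, at 0.08, −0.07 and 0.11 (adjusted p = 0.0370, 0.0107 and 0.00704), and apoptosis genes also passed without a filter (adjusted p = 0.0451). Several lists passed with a single array left out, which unbalances the replicate numbers, and none of these passed in the paired fit with a whole pair left out (lowest adjusted p = 0.0853). Hypoxia genes, for example, had a mean signal of 7.86 in control 2 and 7.87 in BATF3 shRNA array 2, the lowest of the 6 arrays. Without control 2 the lists that passed were hypoxia at −0.38, glycolysis at −0.26 and ribosomal proteins at −0.06. Without BATF3 shRNA array 2 they were hypoxia at 0.32, DNA replication at −0.11, AP-1 genes at 0.13 and apoptosis genes at 0.10. Without control 1, DNA replication passed at −0.09 and AP-1 genes at 0.09, without control 3 apoptosis genes at 0.10, and without BATF3 shRNA array 3 oxidative phosphorylation at 0.11.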

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

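The alternatives to the paired fit, the random block and the removal of shared list members were chosen after the data were seen. The number of genes called was 0 under each alternative without a block and 20 with the replicate block; with the number as a random block it was 0. MYC did not pass in any fit run, with differences from −0.03 to −0.30 over the single arrays left out and adjusted p of at least 0.0876 in the alternatives to the paired fit. The MYC target shift was −0.0881 with adjusted p = 0.719 with an estimated correlation and 0.777 with fry, and it ranged from −0.132 to −0.0257 over the arrays left out, not passing without control 2 or BATF3 shRNA array 1. The 11 lists became 0 with an estimated correlation, 0 with fry, and 2 to 12 over the arrays left out, with 2 without BATF3 shRNA array 1; the 75th percentile filter gave 14, and leaving out shared members gave 8, of which 3 were raised and 5 lowered. Starting from the paired fit, the 20 genes became 0 without the intensity trend, 1 without a filter, 0 at an absolute log2 of at least 1, 0 among probe sets, and 0 to 100 over the pairs left out; quantile normalization gave 24, which held all 20. The paired MYC target shift ranged from −0.104 to −0.0576 over the pairs left out, not passing without the pair of replicate 1 (adjusted p = 0.0862), and stayed at −0.0881 with adjusted p = 0.610 with an estimated correlation and 0.273 with fry. The 12 lists of the paired fit became 0 with an estimated correlation, 0 with fry, and 1 to 11 over the pairs left out. The hypoxia shift ranged from −0.381 to 0.315 over the arrays left out and changed direction without BATF3 shRNA array 2, without control 1 (0.116) and without control 3 (0.193), where the replicate numbers are unbalanced. Leaving out arrays reduces the samples; the cause of the other changes was not tested. Apart from the genes and the apoptosis list, the block changed no other call. Other pseudocounts and probe set suffixes could not be run on these values, and BATF3 has no value under any setting. For the 24 lists other than the MYC targets, over the normalization, prior, filter, probe set, block and left-out array settings but not the estimated correlation and fry, which ended every call, 271 values stayed on their side of the threshold, 23 no longer passed, 15 newly passed and 1 passed in the opposite direction. Of the 271, 23 changed sign, each of a list that did not pass.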

Other observations

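The random-list comparisons of the MYC target, integrated stress and NF-kB lists were chosen after their shifts had been seen, so their shares do not measure chance. The second hypoxia list was written after the pattern it tests had been seen but before its own values were. Hypoxia genes separated the cultures by replicate number far more than by shRNA. In the paired model 1443 of 10028 genes differed between the replicate numbers (adjusted p under 0.05), 81 of them over a log2 range of at least 1, against 20 genes for the shRNA. Of 12 measured hypoxia genes, 11 were among the 1443, and their mean log2 signal was 8.88, 7.87 and 8.94 in replicate numbers 1, 2 and 3, a range of 1.07 beside a knockdown difference of −0.02. On that list, the mitophagy receptor gene BNIP3L stood at 12.3, 10.9 and 12.3, and DDIT4, an inhibitor of mTORC1, at 8.70, 6.73 and 8.87. The lipid droplet gene HILPDA, not on the list, had the smallest p between the numbers, at 11.4, 9.22 and 11.4. Glycolysis genes followed with means of 9.74, 9.25 and 9.84, with 7 of 9 among the 1443. MYC target means ranged over 0.166 between the numbers, beside a knockdown difference of −0.0881.

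The cultures of replicate number 2 may have had a weaker hypoxia response in both arms. A second list of hypoxia-induced genes, sharing none with the hypoxia and glycolysis lists, was lower in replicate number 2 by a mean log2 of −0.43, with 11 of 11 measured genes below 0, and 0 of 10000 random lists matched on signal lay as low. The labels give no culture density, oxygen level or day, so no source of the difference was tested.

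Among probe sets unnamed here, those with the smallest paired p in each direction were picked. Of these, 16699106 (−0.89) and 16729126 (−0.68) were lower and 16771549 (1.37) and 16986937 (0.74) higher in 3 of 3 pairs, with paired limma adjusted p from 0.236 to 0.254.

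The MYC target list was lower in the BATF3 shRNA arrays by 0.0881. A signal-level bias between arrays is argued against, since 10000 random lists matched on mean signal averaged 0.006, with 0 as low. Additive variation shared by arrays of one replicate number cancels in the difference by design, since each number holds 1 array of each group. The 3 pairs lay at −0.149, −0.0585 and −0.0566. Camera kept the call with the block (adjusted p = 0.00137, and 0.610 with an estimated correlation), which is no separate test of that variation. The fry value set as its test (p = 0.0838, where an exact test of 3 pairs cannot go below 0.25) measures the spread of the difference between pairs instead. That fry p lay on the side that the rule set in advance took as going with shared variation. With 10 splits of the 6 arrays a share under 0.05 cannot be reached; 4 of the 10 gave a camera p as small, with a shift of 0.0881 for the real split and up to 0.130 for another. A difference confined to BATF3 shRNA array 1 or its pair would not cancel. That stays open, since without this array the list stood at −0.0257 (camera adjusted p = 0.739). An effect of the BATF3 hairpin on MYC activity, which the design names, also stays open.

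The integrated stress list was lower by 0.168. A signal-level bias between arrays is argued against, since 10000 matched random lists averaged 0.002, with 0 as low. Additive variation shared by a replicate number cancels in the same way, with pairs at −0.197, −0.0996 and −0.208. Camera gave an adjusted p = 0.000448 with the block (adjusted p = 0.610 with an estimated correlation). For the spread between pairs, fry gave p = 0.0343, or 0.273 adjusted over the 25 lists, where an exact test of 3 pairs cannot go below 0.25. The 10 splits are too few for a share under 0.05, with 1 giving a p as small, a real shift of 0.168 and a highest other of 0.160. A lower amino acid stress response to BATF3 knockdown is a hypothesis these arrays leave open, with a single hairpin in each arm.

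The NF-kB list was higher by 0.110, though by 0.03 without members that other lists hold. The 10000 matched random lists averaged 0.007, which argues against a signal-level bias between arrays, and 2 of them (0.02%) lay as high. Additive variation shared by a replicate number cancels here too, with pairs at 0.177, 0.0666 and 0.0875. Camera gave an adjusted p = 0.00169 with the block (0.610 with an estimated correlation). For the spread between pairs fry gave p = 0.0776, where an exact test cannot go below 0.25. That fry p also lay on the side that the rule set in advance took as going with shared variation. The 10 splits are too few for a share under 0.05, with 1 giving a p as small, a real shift of 0.110 and a highest other of 0.106. The split at 0.106 kept both arrays of replicate number 2 on 1 side and both of number 3 on the other. The other splits that keep each pair apart reached at most 0.0660. A difference confined to BATF3 shRNA array 1 or its pair would not cancel. Without this array the list stood at 0.0732 (camera adjusted p = 0.111). Such a difference and an effect of the BATF3 hairpin stay open.

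For the counts of calls the splits are also too few for a share under 0.05. Without the pairing, all 10 splits gave 0 genes, and 2 of the 10 gave at least as many lists as the real split, with 11 for the real split and 12 for the highest other. The split with 12 kept both arrays of replicate number 2 on 1 side and both of number 3 on the other. The other splits that keep each pair apart gave 3, 0 and 0 lists. Of the 4 ways to part the 3 pairs, 1 gave as many genes (20, highest other 0) and 1 as many lists (12, highest other 3).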
